A study of Aspergillus niger with 32 samples.

How the data were processed

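Gene expression of Aspergillus niger was measured on 1-colour Agilent arrays (Cy3 label) after 72 h of culture at 28 °C and 175 rpm. Biofilms grew on polyester cloth and submerged cultures grew free in the medium. Each culture form was grown on glucose, maltose, lactose or xylose at 1% in 70 mL of medium. The series lists 32 samples in 8 groups. Groups were taken from the sample titles.

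The scanner files deposited by the authors hold, per the file headers, the processed signal intensity of each spot after background subtraction and detrending, with no scaling between arrays. They were made with Agilent Feature Extraction 9.5.1.1 for the lactose and xylose arrays and 11.5.1.1 for the maltose and glucose arrays. The extraction protocol of the glucose arrays differed from that of the others. The value table of the authors is on the log2 scale. Checked against the scanner files, it held for each gene the mean log2 signal of the spots well above background (of all spots where none was), minus a constant per array near the 75th percentile. Its column medians lay between -2.78 and -2.03. On each complete array at least 99.1% of the 14104 genes matched this within 0.001. The flags per spot (other than intensity) are 0 or 1 in the deposited files.

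Scanner files were available for 31 arrays. No scanner file of lactose biofilm replicate 1 was used here, so that group has 3 arrays. The file of xylose submerged replicate 4 holds values for only part of the array, and 8511 of the 12601 genes tested had a value there. Each complete file holds 45220 spots and 42310 different non-control probes for 14104 genes, with 3 probes for most genes. The 31 arrays lay on 8 slides read in 3 scan sessions. Lactose and xylose arrays shared 4 slides and a session. Maltose arrays had 2 slides and a session of their own, and so did the glucose arrays. Both culture forms of a carbon source lay on the same slides.

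Spots flagged as outliers or controls were left out. The log2 processed signal of each array was reduced by the 75th percentile of its non-control probes. A probe was kept when it was well above background on at least 3 arrays of any 1 group, which left 35774 probes for 12601 genes. Spots of 1 probe were averaged, and then the kept probes of a gene. Among called genes with several kept probes, all probes went in the same direction in 98.6% or more of the genes in each comparison of culture forms or of xylose with lactose, and in 95.7% or more against glucose. Of the genes named by the rule below and called, the probes disagreed for phyB in the mean biofilm comparison (log2 from -0.13 to 1.16) and for tpsA in maltose minus glucose (from -0.16 to 0.58).

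Group means were fitted with limma 3.58.1 in R 4.3.3 over all 31 arrays. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Tables were handled with the data.table package (version 1.17.8) and figures drawn with matplotlib 3.10.9. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, and a gene was called at an adjusted p below 0.05. The comparisons were biofilm minus submerged on each carbon source and as the mean of the 4, the moderated F for a biofilm effect that differs between sources, xylose minus lactose within each culture form, and maltose, lactose and xylose minus glucose as means of both forms. Changes are log2 differences with their standard error. A group in which a gene was well above background on no array gives a bound, computed after raising its value on each array of that group to at least the lowest well-above-background value of the array. In means over several groups the lower side of each pair was raised in this way, and no bound is given where both sides of a pair, or the higher side, were dim. The number of arrays limits the precision, and so does the share of spots above background.

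Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, and were adjusted over the 15 lists with at least 4 tested genes. There were 23 lists with 129 genes, of which 127 were tested. Of these lists 20 were defined before the data were examined. The glycolysis, respiration, ribosomal protein and low oxygen lists were then defined by function text alone. The gene reference lacks such text, so their members were taken by symbol. The lists of peptidases, of central carbon and respiration enzymes, and of trehalose and phosphate genes were made from the symbols of the reference table after the files were opened and before any test. The gene reference pairs IDs with symbols for 130 genes and holds no function text. It names 82 of the list genes. The names of the others come from general knowledge, were not checked against an annotation, and are printed as "listed as". No genome build is named in the files, so no coordinates are given. The symbols aglC, amyA and cpcA occur for several IDs and xynA is used for different genes, so IDs are printed with them.

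The genes named were chosen by a rule fixed before the data were examined. It takes the 12 largest increases and decreases of the mean biofilm comparison that go the same way on all 4 sources and have a symbol or a listed name (11 decreases met it), and 2 genes per direction without a name. It takes the 4 largest changes per direction on each source and in xylose minus lactose, the 3 largest per direction against glucose, and the 6 smallest interaction p-values. It adds up to 4 members of each list per comparison, and in every case cbhA, cbhB, eglA, xlnB, xlnD, xlnR, xyrA, glaA, amyR, lacA, brlA and the listed hydrophobins. The list members against glucose are given as counts and where they reversed.

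The alternatives chosen before the data were examined were the authors' value table with all 32 samples, quantile normalization, median centring, normexp background correction with offset 50, no filter on dim probes, probes well above background on every array, the brightest probe per gene, slide as a fixed or random block, replicate number as a block, array weights, a variance prior with trend and robust, only the groups compared, and leaving out each array. Normexp used the median spot signal on the maltose arrays, whose files lack the mean signal. Array weights were computed gene by gene, because the other method did not converge. A common floor on all arrays (log2 -2.01), leaving out 3 doubtful arrays together (the dimmest, maltose submerged replicate 4; xylose biofilm replicate 3, which correlated least with its group among the xylose arrays; and the incomplete array), and lists with only table-named members were added after seeing the data.

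The procedure was tested on simulated data. These were averaged group means plus normal noise with the measured spread of each gene, and changes were added to 200 of the 12601 genes. Far fewer genes were changed than were called in the measured comparisons, so the shares found may differ in the data. For changes shared by all 4 sources, 2-fold changes were found in 49.3% to 59.7% of the changed genes on single sources and in 97.0% in the mean. Of 4-fold changes, 87.9% to 95.5% were found on single sources. The test for an effect that differs between sources found 17.9% of 2-fold and 68.2% of 4-fold changes made on glucose alone. Of 2-fold changes, xylose minus lactose found 55.2% in submerged cultures and 37.3% in biofilms, and the comparisons against glucose found 74.6% to 79.1%. Changes of 1.5-fold were found in 62.7% of genes in the mean and in 16.4% or fewer on single sources.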

Results

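The arrays measured 12601 genes of Aspergillus niger in biofilm and submerged cultures on 4 carbon sources. There were 4 arrays in each of 7 groups and 3 in the lactose biofilm group. The 75th percentile of the processed signal ranged from 1190 to 2050 on the glucose arrays and from 42.9 to 436 on the others. Spots well above background made up 75.8% to 85.4% of the glucose arrays and 33.4% to 65.7% of the other arrays. The lowest share, 33.4%, was that of maltose submerged replicate 4. Correlations across genes between arrays ranged from 0.910 to 0.996 within groups and from 0.779 to 0.962 between groups. The first 3 principal components held 26.9%, 21.3% and 17.8% of the variance.

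The title of the series names lignocellulose-degrading enzymes of biofilms as its subject, and the comparison of both culture forms addresses which genes differ between them. Averaged over the 4 sources, 3773 genes were higher and 3595 lower in biofilms (limma, adjusted p below 0.05), of which 1005 and 1050 changed at least 2-fold. In biofilms compared with submerged cultures, 3813 genes were higher and 3424 lower on glucose. On maltose 2783 were higher and 2586 lower. On lactose 1439 were higher and 1268 lower. On xylose 2437 were higher and 2755 lower. Limited to the 4857 genes with probes well above background on every array, the totals were 3205 on glucose, 3096 on maltose and 3080 on xylose. The lactose total stayed within 1.5 times its count. Differences between sources in these counts thus also depend on the probes kept. With each array centred on its median the share of called genes that were higher moved from 51.8% to 40.6% on maltose, from 46.9% to 53.8% on xylose, from 53.2% to 60.7% on lactose and from 52.7% to 54.6% on glucose, so the balance of higher and lower genes depends on the scaling. The lactose count rests on its 3 biofilm arrays, and without biofilm replicate 2 it was 1739 genes in place of 2707. Within single slides at least 96.6% of the genes called on a source went the same way as in the fit. As the calls came from the same arrays, such agreement is no independent check.

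**Figure D1:**
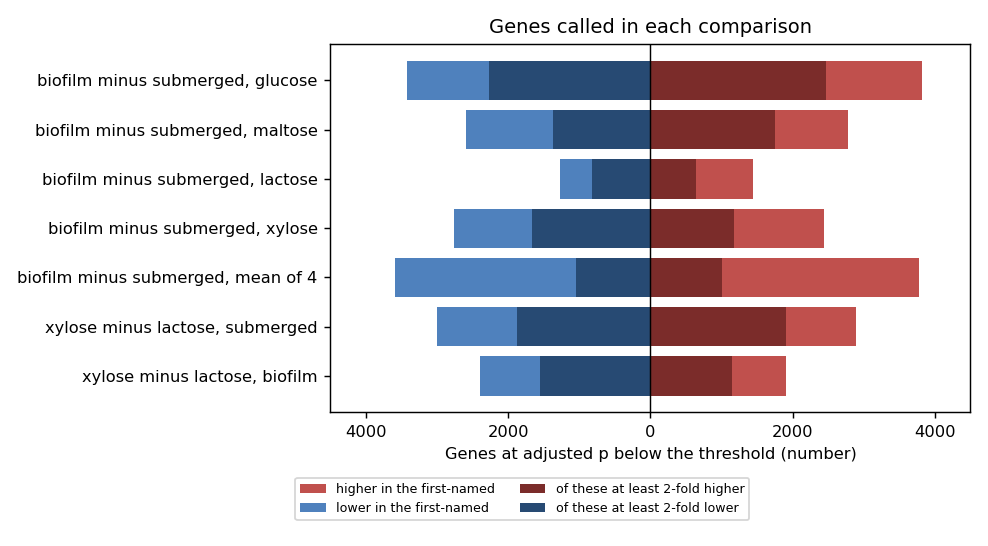
Number of genes called in each of 7 comparisons (horizontal axis), with higher genes to the right, lower genes to the left and changes of at least 2-fold in the darker shade. On glucose 3813 genes were higher and 3424 lower in biofilms, and on lactose 1439 and 1268.

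Among genes with a symbol or listed name that went the same way on all 4 sources, catR (An01g01820) rose most, by a log2 change of 3.14 ± 0.13 (SE, adjusted p 3.47e-17). It was called on every source, at 6.01 on glucose, 3.94 on maltose, 1.51 on lactose and 1.12 on xylose. The aglC gene An09g00270 and pelB (An03g00190) were not well above background in a submerged group, and with that group at its floor rose by at least 2.76 and 1.88 (fitted 2.88 and 2.05). The gene rhgB (An14g04200) rose by a fitted 2.37 ± 0.22, with both lactose groups not well above background. An16g06800 (listed as eglB) rose by 1.96 ± 0.12, eglA (An14g02760) by 1.71 ± 0.11, pyc (An04g02090) by 1.68 ± 0.10, mndA (An11g06540) by 1.55 ± 0.13, pfkA (An18g01670) by 1.495 ± 0.131 and tpiA (An14g04920) by 1.47 ± 0.10. The other aglC gene, An09g00260, had a fitted rise of 1.88 ± 0.22, and plyA (An10g00870) of 1.46 ± 0.34. An09g00260 was not well above background on any maltose or xylose array, and plyA on none of the xylose arrays, so neither has a bound. The gene plyA was called on glucose alone (3.93 ± 0.66). Not called on lactose were rhgB, pelB (0.05), An16g06800 (0.47), mndA (0.25), pfkA (0.60) and plyA. Without a name, An02g00740 rose by at least 4.08 (fitted 4.44) and An14g05110 by at least 3.71 (fitted 4.07), with the submerged maltose and xylose groups at their floor.

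The largest decrease of a named gene was that of An08g09880 (listed as a hydrophobin), fitted at -4.87 ± 0.26 (adjusted p 7.42e-15) and at -4.39 with the lactose and xylose biofilms at their floor, so at least 21.0-fold. On glucose it was at -9.78 ± 0.50, from a level of 4.89 in submerged cultures to -4.89 in biofilms. On maltose it was not called, with -0.13 and -2.22 within the maltose slides. In lactose biofilms it was not well above background on any array, so it was at least 40.8-fold lower there. The mean decreases of rgaeA (An09g02160), An01g10540 (listed as brlA) and cbhB (An01g11660) were -2.32 ± 0.31, -1.88 ± 0.13 and -1.77 ± 0.17. That of cbhB was carried by glucose, with -5.19 there, -1.07 on xylose, and -0.71 on lactose and -0.09 on maltose (both not called). That of rgaeA was carried by glucose (-5.12) and lactose (-3.57), with -0.14 on maltose and -0.44 on xylose (both not called). Those of aphA (An13g01750), An07g03340 (listed as a hydrophobin) and An14g02670 (listed as an AA9 monooxygenase) were -1.29 ± 0.11, -1.28 ± 0.12 and -1.10 ± 0.16. On maltose neither An07g03340 nor An14g02670 was called. Sox (An09g05940) was at -0.91 ± 0.16 and kexB (An01g08530) at -0.77 ± 0.10. No gene with a symbol or listed name was called lower on all 4 sources, so these means are not decreases called on each source. An02g03160 (listed as flbA) was at least 1.71-fold lower with the maltose biofilm at its floor (fitted -0.82). An14g05370 (listed as brnA) had a fitted mean of -1.57 without a bound, as it was not well above background in 6 of the 8 groups, and was at least 8.41-fold lower on glucose. An01g10540 was not well above background in 5 of the 8 groups, so its fitted mean decrease has no bound. Within slides its change was largest on glucose (-4.45 and -4.29). Without a name, An04g08150 was at least 122-fold lower (fitted -7.32) and An03g01800 at -6.66 or lower with its dim group at the floor (fitted -6.99). Without lactose biofilm replicate 4 the lactose change of rgaeA was -5.13 in place of -3.57.

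**Figure D2:**
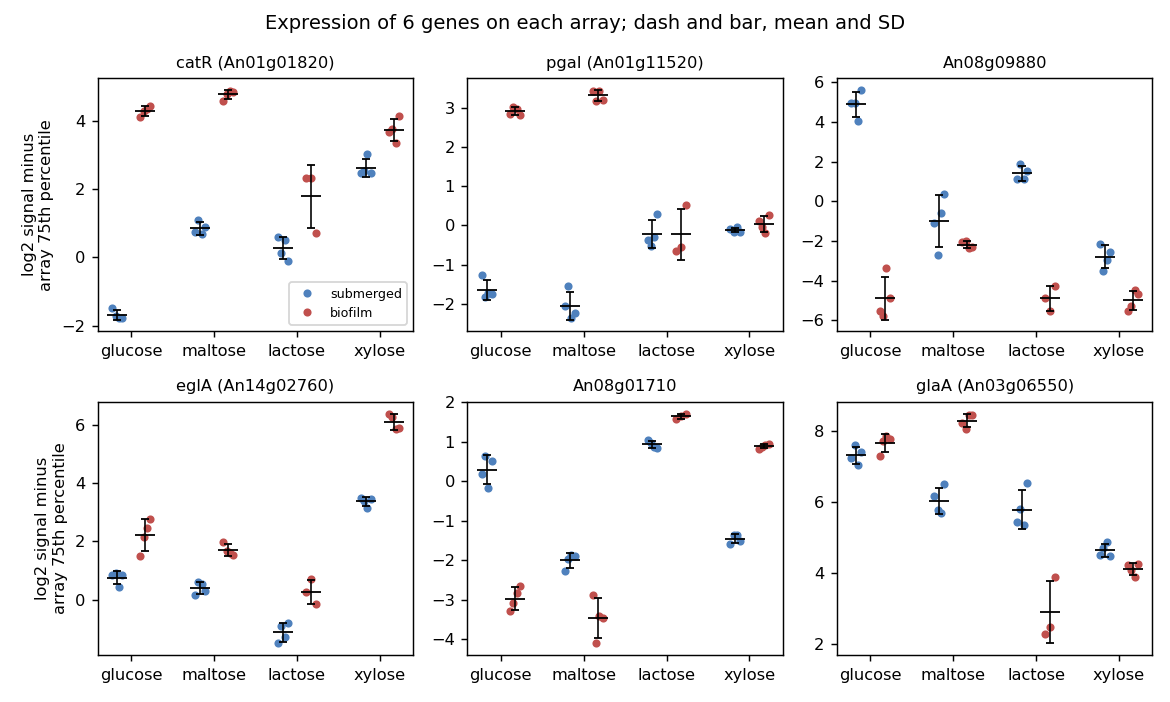
Expression (log2 signal minus the 75th percentile of the array) of 6 genes on each of the 31 arrays, by carbon source, with submerged cultures in blue and biofilms in red. Points are arrays, dashes are group means and bars are SDs. The catR level was higher in biofilms on each source, while An08g01710 was lower on glucose and maltose and higher on lactose and xylose.

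Of the genes named in every case, several went opposite ways on different sources, so their mean over sources describes no single source. The mean of lacA (An01g12150) was 1.497 ± 0.251, with 3.69 ± 0.48 on maltose, 3.549 ± 0.522 on xylose, -2.26 ± 0.52 on lactose and 1.01 ± 0.48 on glucose (not called). The fitted mean of xlnD (An01g09960) was 0.45 ± 0.14 (0.34 with the submerged maltose group at its floor, and not called with normexp), with -2.50 ± 0.28 on glucose, 2.53 ± 0.28 on xylose, at least 1.58-fold higher on maltose and 0.67 ± 0.30 on lactose (not called). The gene cbhA (An07g09330) had a mean of -0.85 ± 0.20, with -2.77 ± 0.40 on glucose, -1.42 on maltose and -0.69 on lactose (not called), but rose by 1.48 ± 0.40 on xylose (adjusted p 0.00358). The gene listed as xlnB (An01g00780) had a mean of -1.07 ± 0.25, with -1.85 on glucose and on lactose, and 0.51 ± 0.51 on xylose (not called). The mean of xlnR (An15g05810) was -0.46 ± 0.11, with -1.49 on glucose, -0.98 on maltose, 0.07 on lactose and 0.54 on xylose (the last pair not called).

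Among the listed hydrophobins, An03g02400 was at 0.03 ± 0.17 in the mean (not called). An01g10940 had a fitted mean of -1.23 (-1.12 with the lactose biofilm at its floor), but was at 1.13 ± 0.31 on glucose, -2.12 ± 0.31 on xylose and at least 7.93-fold lower on lactose. The mean changes of xyrA (An01g03740, -0.21 ± 0.10), glaA (An03g06550, -0.20 ± 0.14) and amyR (An04g06910, -0.07 ± 0.13) were not past the threshold (adjusted p 0.0625, 0.224 and 0.673). On single sources xyrA was at -1.28 on glucose and 0.98 on xylose, glaA at 2.27 on maltose and -2.90 on lactose, and amyR at -1.82 on lactose and 0.99 on xylose, all called.

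On glucose the largest named increases were those of catR (6.01 ± 0.25), pgaI (An01g11520, 4.55 ± 0.21) and both aglC genes (An09g00260, 5.25 ± 0.44, and An09g00270, 4.60 ± 0.42). With the common floor, which makes values under it equal, An09g00260 was at 0.14 and was not called. The named decreases after An08g09880 were abnA (An09g01190, -5.74 ± 0.66), An01g11670 (listed as an endoglucanase, -5.21 ± 0.34) and cbhB (-5.19 ± 0.34). On maltose pgaI rose by 5.36 ± 0.21, pepF (An07g08030) by 4.74 ± 0.34 and catR by 3.94 ± 0.25. The gene pgaII (An15g05370) was at least 13.2-fold higher. On maltose hyl1 (An16g02170, -1.61 ± 0.27), An08g01710 (listed as abfC, -1.46 ± 0.19) and cbhA (An07g09330, -1.42 ± 0.40) fell, and abfB (An15g02300) was at least 3.05-fold lower. With normexp and with the common floor none of these 4 was called on maltose, and pgaII was not called there with normexp.

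On lactose dhbD (An07g02050) rose by 2.88 ± 0.37, abfB by 2.21 ± 0.34, AO-I (An09g01550) by 2.09 ± 0.36 and An09g00270 by 1.77 ± 0.45. With only the lactose groups in the fit An09g00270 was not called. An07g03340 was at -3.53 ± 0.25. The gene with the symbol proctase-A (An01g00530) was at -9.25 ± 1.02, but its lactose biofilm arrays were at -3.002 (replicate 2), -3.75 (replicate 3) and 4.55 (replicate 4), and the change was -11.89 without replicate 4, -7.74 without replicate 3 and -8.11 without replicate 2. Likewise rgaeA (An09g02160) was at -3.57 ± 0.65, and at -5.13 without biofilm replicate 4 and -2.71 without replicate 3, so the size of both changes depends on single arrays. On xylose pepA (An14g04710) rose by 5.88 ± 0.57, pgaII by 5.36 ± 0.44, An03g00940 (symbol xynA) by 4.22 ± 0.40 and axhA (An03g00960) by 3.81 ± 0.42. On xylose An04g09890 (listed as agsA) was at -2.30 ± 0.35, An04g08600 (listed as araR) at -2.27 ± 0.30 and goxC (An01g14740) at -2.19 ± 0.41. An08g09880 was at least 2.39-fold lower on xylose, but with normexp and with the common floor it was not called. With normexp AO-I was not called on lactose, and goxC not on xylose.

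Across genes, which are not independent replicates, the biofilm changes of pairs of sources correlated with Pearson's r from 0.190 (glucose and xylose) to 0.573 (glucose and maltose). Spearman's rho for these pairs was 0.211 and 0.533. For the other pairs r lay between 0.306 and 0.370. Of the genes called on both glucose and maltose 87.4% went the same way, and of those called on both glucose and xylose 69.5%. There were 346 genes higher in biofilms on all 4 sources, where 18.6 would be found if the sources were independent, and 337 lower, against 15.5. The calls of a gene share an estimate of its spread, which these expected numbers ignore, so they can be too low. In contrast 1884 genes were higher on some sources and lower on others, and 2647 were called on none. With a symbol, 13 genes were higher on all 4 sources, namely catR, icdA, ostA, pyc, nuo51, cpy, the aglC gene An09g00270, httA, eglA, argB, cox5, tpiA and Balu-42. These were listed because their group was small, after their values were seen. No gene with a symbol or listed name was called lower on all 4 sources.

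The biofilm effect differed between sources at 7719 of 12601 genes (moderated F). The xylose and lactose effects, measured on the same slides, differed at 2720 genes. The glucose effect differed from that of maltose at 4684 genes, of lactose at 4783 and of xylose at 5592. The smallest p-values of named genes were those of pgaI, An08g01710, An12g00030 (listed as xdhA), hyl1, catR and abfB (adjusted p from 4.6e-14 to 2.57e-11). On lactose pgaI was at 0.00 ± 0.23 and on xylose at 0.16 ± 0.21. An08g01710 was at -3.27 on glucose, 0.72 on lactose and 2.35 on xylose. An12g00030 was at -3.41 on glucose, -1.32 on maltose and 1.82 on xylose. The change of hyl1 was -4.60 on glucose and 1.41 on xylose, and that of abfB was -3.03 on glucose and 2.55 on xylose.

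Of 15 gene lists, 5 passed the camera test in the mean biofilm comparison. The pectin list was higher (adjusted p 8.53e-06, median log2 change 1.71), with 11 of 14 genes higher and 1 lower, both over all genes tested and adjusted over the list alone, and a median of 1.48 with dim groups at their floor. It alone held with an estimated correlation (0.0223). The glycolysis list (0.00629, median 0.88, 5 of 6 higher), the peptidase list (0.0363, 1.00, 4 of 6 higher) and the central carbon and respiration list (0.00167, 0.85, 8 of 10 higher) were higher. The hydrophobin list was lower (0.00546, -1.26, 3 of 4 lower), but on maltose 0 of its 4 genes were called. Fry, which tests whether the genes of a list move on balance in a direction, gave these 5 lists adjusted p from 3.36e-11 to 5.04e-07, but does not set them apart. It also passed 6 of the other 10 lists, the conidiation (5.59e-06), xylose and arabinose catabolism (7.35e-05) and cell wall lists (0.00189) as lower and the protease (0.000392), galactoside and secretion lists (both 0.000502) as higher. The counts of genes called over all genes tested and adjusted over the list alone were equal in the mean comparison for each list but the ribosomal protein list (1 and 2 of 2 genes higher).

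The remaining lists did not pass with camera in the mean comparison. Of the cellulose list, 5 of 14 genes were higher and 4 lower, and of the xylan list 4 of 13 higher and 5 lower. The xylose and arabinose catabolism list had 3 of 6 lower, the starch and maltose list 1 of 6 higher, and the galactoside and galactose list 4 of 8 higher and 2 lower. Of the conidiation list 4 of 7 were lower, and of the cell wall list 3 of 4. The secretion and folding list had 4 of 6 higher and 1 lower, the protease list 3 of 5 higher and 1 lower, and the trehalose and phosphate list 1 higher and 1 lower of 5. Median, mean and test differed in sign for the cellulose, xylan, starch and trehalose lists, whose adjusted p was at least 0.770. Too small for a test were the mannan list (1 higher and 1 lower of 2 genes), the inulin and sucrose list (0 called of 3), the autolysis list (0 of 2), the sugar transporter list (1 higher of 1), the oxidative enzyme list (1 higher of 2), the respiration list (2 higher of 2), the ribosomal protein list and the low oxygen list (1 higher of 1).

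On single sources 4 lists passed camera on glucose, 6 on maltose, 4 on lactose and 11 on xylose, of which 2 on each source also passed with an estimated correlation. These were the pectin and the xylose catabolism lists on glucose, the pectin and peptidase lists on maltose, the starch and hydrophobin lists on lactose, and the galactoside and peptidase lists on xylose. For the peptidase list the estimate was negative (-0.091) and taken as no correlation, so before adjustment this test was no stricter than that at the preset 0.01. The pectin list was higher on glucose, maltose and xylose with medians of 2.39, 2.35 and 0.88, but not on lactose, where 0 of 14 genes were higher and 4 lower (median -0.12, adjusted p 0.218). The xylan list was lower on glucose (median -1.49) and higher on xylose (2.30), and so was the xylose catabolism list (-1.28 and 1.21). The starch list was higher on maltose (2.44) and lower on lactose (-2.79), and the hydrophobin list was lower on lactose (-3.47). Within slides the starch list median on lactose lay between -3.45 and -2.09, and the xylan list median on xylose between 2.06 and 2.36. In all, the 42 list calls of single comparisons had the same sign of the median in each slide. The slides hold the same arrays that gave the calls, so this is no independent check.

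**Figure D3:**
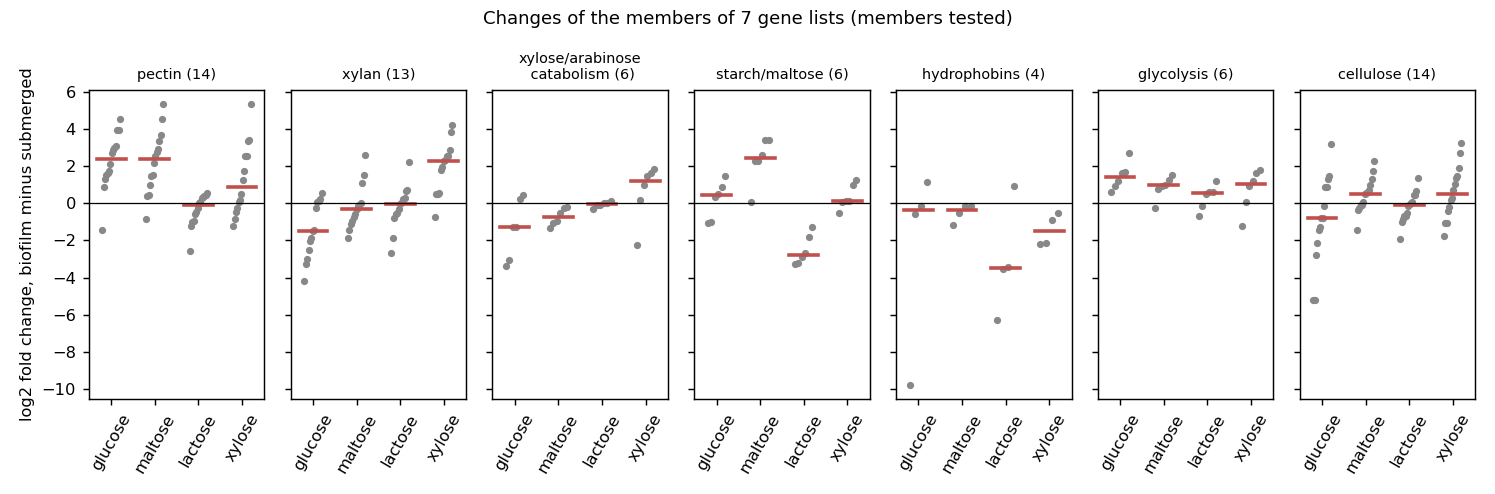
Log2 fold change (biofilm minus submerged, vertical axis) of each tested member of 7 gene lists on each source, as grey points, with the list median as a red line. The starch and maltose list had a median of 2.44 on maltose and -2.79 on lactose.

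Xylose was compared with lactose because arrays of both shared slides. In submerged cultures 2890 genes were higher and 2999 lower on xylose, and in biofilms 1902 were higher and 2399 lower. The share of called genes that were higher was 49.1% in submerged cultures and 44.2% in biofilms, and 57.4% and 57.1% with median centring. An14g07390 (listed as xynA) was at least 618-fold higher in submerged cultures and at least 2049-fold higher in biofilms. In submerged cultures xyrA (An01g03740) rose by 6.45 ± 0.19, An01g00780 (symbol xynB) by 5.78 ± 0.51 and cbhB (An01g11660) by 4.51 ± 0.34. There pepA (An14g04710) was at -9.84 ± 0.57, proctase-A (An01g00530) at -6.93 ± 1.02, aglA (An06g00170) at -6.40 ± 0.40 and dhbD (An07g02050) at -6.10 ± 0.35. In biofilms An01g00780 rose by 8.13 ± 0.51 (8.83 without lactose replicate 4) and aceA (An12g05010) by 8.11 ± 0.64 (9.57 without lactose replicate 4, 7.37 without lactose replicate 3), and An03g00940 was at least 157-fold higher. In biofilms dhbD was at -7.96 ± 0.37, abnA (An09g01190) at -4.89 ± 0.71 and An12g07450 (listed as mstA) at -4.21 ± 0.39, and AO-I (An09g01550) was at least 13.8-fold lower. Of the 15 lists 9 passed camera in submerged cultures and 8 in biofilms, with the xylan list at a median of 6.11 in biofilms. With an estimated correlation 2 and 4 passed, the xylose catabolism list in both forms, the protease list (lower) in submerged cultures, and the cellulose, xylan and pectin lists in biofilms.

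Against glucose, maltose had 5238 genes higher and 3091 lower, lactose 5549 and 2977, and xylose 5202 and 3108. Glucose arrays lay on slides and in a scan session of their own, with another extraction protocol, so carbon source and batch cannot be told apart here. In 1584, 1317 and 994 of these calls the higher side was not well above background. With quantile normalization the share of higher genes moved from 62.9%, 65.1% and 62.6% to 42.9%, 44.2% and 42.6%, and with normexp to 81.3%, 83.7% and 83.3%, so it depends on the processing. The gene faeA (An09g00120) was not well above background on any glucose array and was at least 106-fold higher on xylose (fitted 7.86). Xylose minus glucose was at 12.59 ± 0.29 for An14g07390 and 7.30 ± 0.14 for xyrA (An01g03740), and at -6.10 ± 0.31 for the amyA gene An12g06930, -6.09 ± 0.26 for aglU (An04g06920) and -5.92 ± 0.37 for An11g03340 (listed as aamA). Lactose minus glucose was at 4.67 ± 0.25 for dhbD (An07g02050) and -5.31 ± 0.25 for cbhB (An01g11660). With lactose biofilms at their floor, phyB (An08g11030) was at least 30.8-fold lower (fitted -5.27) and An01g11670 at least 22.0-fold lower (fitted -4.88). Maltose minus glucose was at 2.04 ± 0.21 for Sox (An09g05940), 1.96 ± 0.14 for the cpcA gene An01g07890, -4.84 ± 0.37 for pepA (An14g04710), -4.45 ± 0.67 for proctase-A (An01g00530) and -3.61 ± 0.24 for An01g11670. The fitted changes of faeA on maltose and lactose (3.84 and 3.91) and of inu1 (An12g08280, 3.76 on lactose) became 0.000 with the common floor, under which their group means lay, and faeA was well above background in no group of these comparisons.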

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

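The tests of the scan session, the 3 doubtful arrays and the floor were chosen after the result was seen.

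In groups of 4 arrays the farthest array was tested with Dixon's ratio, and 6 of 122 groups had an array farther from the others than its 95% critical value, where chance gives about 1 in 20 groups. Of these, 3 were submerged glucose replicate 2. The log2 of its 75th percentile was 10.83, against 10.65 to 10.68 on the other arrays. Its level of eglA was 0.45 (others 0.85 to 0.92) and of xlnR 1.04 (others 1.34 to 1.39). Maltose biofilm replicate 2 had a level of xlnD of -3.87, against -2.85 to -2.64. Xylose submerged replicate 4, the incomplete array, had a level of amyR of -2.87, against -2.32 to -2.21. Xylose biofilm replicate 3 had a level of An07g03340 of -2.96, against -2.19 to -2.13.

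The biofilm effect differed between carbon sources at 7719 genes by the moderated F, with adjusted p of 4.6e-14 for pgaI, 7.05e-14 for An08g01710, 4.57e-13 for An12g00030, 6.55e-12 for hyl1, 1.77e-11 for catR and 2.57e-11 for abfB. As the whole cause, the scan session and extraction protocol are argued against by the xylose and lactose effects, which share slides and session and differed at 21.6% of the genes. The 3 doubtful arrays are argued against because 98.2% of the called genes were also called without them. Maltose submerged replicate 2 (array weight 0.216) and lactose biofilm replicate 4 (0.235) were left out only singly. Leaving out each array in turn gave 7315 to 8840 genes. With a common floor 74.0% were also called, but values it makes equal have no spread, which can ease calls. So that share decides nothing about genes near the floor. They are argued against as the whole cause by the 3846 of 4857 genes called with only probes well above background on every array. With normexp 3130 genes were called. Carbon source, which the design names, stays open as a biological explanation, and so do unrecorded differences in growth at 72 h, which were not tested. Which part of the differences from glucose and maltose belongs to the batch was not tested.

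For each comparison the arrays were regrouped in 35 splits, or in 100 random splits where there were more. The real grouping was the only 1 of the splits with as many genes. With 35 splits, 1 in 35 is the smallest share that can be reached, so chance is argued against but not excluded. The other splits mix arrays of different groups, which widens the spread, so they were likely to call fewer genes. Against glucose the splits cannot separate the carbon source from the scan session. On glucose the real grouping called 7237 genes and the highest other split 15. The pairs were 5369 and 3240 on maltose, 2707 and 1444 on lactose, 5192 and 1067 on xylose, 7368 and 1335 in the mean, and 7719 and 3825 for the differing effect. They were 5889 and 1851 for xylose minus lactose in submerged cultures and 4301 and 2742 in biofilms. Against glucose they were 8329 and 6761 for maltose, 8526 and 5802 for lactose, and 8310 and 6255 for xylose.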

How the results depend on the processing

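The common floor, leaving out 3 arrays together and the lists of table-named members were chosen after seeing the data. Of 362 alternative counts and mean correlations 333 stayed within 1.5 times the reported count or within the error of the correlation. Of 14748 alternative values of 501 results for genes named by the rule, 14189 kept their direction and side of the threshold, 353 lost their call, 164 gained one and 42 reversed. Without normexp and the common floor, 10 of 13746 reversed. Of 103 results chosen by size or named in every case, 1 lost its call under another setting (An09g00270 on lactose with only the groups compared, adjusted p 0.0645), 11 with normexp and 12 with the common floor. Of 1277 alternative list tests 1196 kept direction and side, 73 lost their call, 7 gained one and 1 reversed.

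With only probes well above background on every array, which left 4857 genes to test, counts were 3205 on glucose, 3096 on maltose, 3080 on xylose, 3564 in the mean and 3846 for the differing effect. They were 3156 and 2460 for xylose minus lactose in submerged cultures and biofilms, and 3279, 3284 and 3363 for maltose, lactose and xylose against glucose. The mean correlation between sources was 0.399 (reported 0.343, jackknife SE 0.028). With normexp, counts were 4417 on glucose, 973 on maltose, 438 on lactose, 1826 on xylose, 3772 in the mean, 3130 for the differing effect, and 2504 and 1348 for xylose minus lactose in submerged cultures and biofilms. With normexp 3 lists passed in the mean and the mean correlation was 0.313. The normexp offset of 50 lies within the median processed signals of the maltose, lactose and xylose arrays (7.38 to 71.7). It lies below those of the glucose arrays (190 to 296). An offset draws low log2 signals together, so it is a candidate explanation of the lower counts with normexp. Another offset was not tried, so the cause was not tested. With an estimated inter-gene correlation 1 list passed.

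Array weights (from 0.0916, on maltose submerged replicate 4, to 6.03) gave 5282 genes on lactose and 6637 for xylose minus lactose in biofilms; the cause was not tested. With only the groups compared, fewer arrays estimate the spread, and 1748 genes were called on lactose. With the common floor, 5205, 5201 and 5130 genes were called for maltose, lactose and xylose against glucose, since values under the floor are made equal.

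Without a single array, counts ranged from 6742 to 6895 on glucose, 4936 to 6004 on maltose, 1739 (without biofilm replicate 2) to 3137 on lactose and 4694 to 5098 on xylose. They ranged from 7100 to 7880 in the mean, 7315 to 8840 for the differing effect, 5398 to 5748 and 3659 to 4107 for xylose minus lactose in submerged cultures and biofilms, 8012 to 8566 for maltose, 8104 to 8402 for lactose and 7924 to 8235 for xylose against glucose, and 4 to 6 for lists passing.

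Results that reversed follow. In the mean biofilm comparison An01g10920 was at 0.36 with the common floor (reported -0.64), An08g11030 at -0.13 with the brightest probe per gene (0.50), and the xylan list was higher with the common floor (adjusted p 0.00205). In xylose minus lactose An09g00260 was at 0.005 with the common floor in submerged cultures (-2.31), and An01g08900 at 0.006 with normexp in biofilms (-0.69). For lactose minus glucose An02g03160 was at 0.001 with the common floor.

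With normexp the median change of all genes rose against glucose from 0.23, 0.28 and 0.24 to 1.21, 0.92 and 0.93 on maltose, lactose and xylose. Reversed values in maltose minus glucose were An01g00160 -0.56, An01g03460 -1.04, An01g14740 2.15, An02g03160 1.35, An02g12430 0.25, An03g00960 0.58, An06g00290 2.30, An06g01550 -0.28, An08g00970 -0.81, An08g06580 0.56, An08g10510 -0.49, An08g11070 1.94, An11g04180 -0.61, An11g06540 0.64, An12g00950 0.15, An12g05010 0.37, An14g05820 0.65, An16g01830 -0.38, An17g01530 -0.18 and An18g02020 -0.009. In lactose minus glucose they were An01g14740 1.33, An02g03160 0.75, An08g11070 1.37 and An16g04160 0.14. In xylose minus glucose they were An03g00190 0.23, An08g11070 1.13, An09g05730 0.28 and An16g04160 0.26.

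With quantile normalization the median change of all genes against glucose moved to -0.12, -0.10 and -0.09. Reversed values in maltose minus glucose were An07g08640 -0.10, An09g03780 -0.87, An11g03200 -0.006 and An14g05370 -0.30. In lactose minus glucose they were An07g08640 -0.071 and An11g01120 -0.23, and in xylose minus glucose An07g08640 -0.14, An09g03780 -0.061 and An14g05370 -0.26. For the reversals not made by a floor or a choice of probe, the cause was not tested.

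With median centring the median change of all genes moved from -0.08 to -0.27 on maltose, and from -0.11 to 0.09 for xylose minus lactose in biofilms. The same-numbered cultures were not paired by their values (the correlation of residuals was above 0.1 in 2 of 4 pairs on glucose, 1 of 4 on maltose and 0 on lactose and xylose), so the replicate block was kept as an alternative. The consensus correlation within slides was -0.0304. Signal over background limits what can be measured, since the lowest value well above background was between -7.91 and -7.09 on glucose arrays and between -5.02 and -2.01 on the others.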

Other observations

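The tests of the common floor, the carbon source and amyR were chosen after the result was seen, as were the permutation p-values of adjacent pairs and the runs of genes.

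More genes were higher than lower on maltose, lactose and xylose than on glucose. With a common floor on all arrays the share of higher genes was 51.0% on maltose, 50.6% on lactose and 47.7% on xylose. That floor (log2 -2.01) lies above each column median of the authors' value table (-2.78 to -2.03), so it makes much of each array equal. With only probes well above background on every array it was 62.7%, 48.0% and 54.5%. A lower measurable floor on the glucose arrays is thus a candidate explanation of the excess on lactose and xylose, where no share was above 54.5%. On maltose the settings disagree (51.0% and 62.7%), and the excess there stays open. With quantile normalization the shares were 42.9%, 44.2% and 42.6%, and with normexp 81.3%, 83.7% and 83.3%, so the excess also depends on the processing. Whether the carbon source itself contributes cannot be told apart from the scan session, because 0 sessions held glucose and another source.

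The starch and maltose list was lower in lactose biofilms and higher in maltose biofilms. With camera at an estimated inter-gene correlation the list passed on lactose (adjusted p 0.0137). On maltose it did not (0.205, against 0.00399 at the preset correlation), so the camera call there rests on the preset correlation. On maltose 5 of its 6 members were called higher, each at least 2-fold, and fry gave an adjusted p of 0.000281. A single lactose array is argued against, since the median without each lactose array stayed at or below -2.40, and a single maltose array, since the median without each stayed at or above 2.30. The lactose biofilm sample without a scanner file went the same way in the authors' value table, with a median of -2.41 against the submerged lactose samples. A rise of amyR (An04g06910) of at least 2-fold in maltose biofilms is argued against, as its log2 change plus 2 standard errors was 0.57. On lactose amyR, itself a member of the list, changed by -1.82 ± 0.28 (adjusted p 2.37e-05), and all 6 members were lower, so whether amyR had a part in the lactose decrease stays open. Other biological explanations, such as sugar left in the medium at 72 h, were not tested.

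Neighbouring genes were tested as a hypothesis. Adjacent means next to each other on a chromosome among the 12559 tested genes that were placed, so untested genes may lie between them. Across 12551 adjacent pairs of genes the mean biofilm changes correlated with r = 0.128, above the highest of 10000 shuffled orders (0.0343; one-sided permutation p 1e-04, the smallest they can give). Genes next to each other may thus change together, and shared probes or overlapping transcripts were not tested as a cause. The second hypothesis, that genes higher on all 4 sources lie together beyond every shuffled order, was negative by the bar set beforehand. They made 18 adjacent pairs, with a mean of 9.33 and a highest of 22 in the shuffled orders (one-sided permutation p 0.0052), and genes lower on all 4 sources made 15, with a mean of 8.96 and a highest of 22 (p 0.037). So 18 was above the mean of the shuffled orders but inside their range. At least 5 adjacent genes, all called and 2-fold changed in a direction in the mean, occurred in 2 runs (mean 0.07 and highest 2 in 1000 shuffled orders, so inside their range), from An04g07760 to An04g07810 (higher, median 1.97) and from An12g09960 to An12g10000 (lower, median -1.43). The longest run, of 5 genes, was also inside the range (mean 3.73, highest 6), and 0 genes of these runs were called on all 4 sources.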
